A study of Homo sapiens with 6 samples.

How the data were processed

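RNA was sequenced from human T cells activated in culture with antibodies to CD3 and CD28 for 72 h, with 100 pM RTA-408 or without it, with 3 libraries in each group. RTA-408 is omaveloxolone, a synthetic triterpenoid that activates NRF2, the transcription factor encoded by NFE2L2. The sample titles number the libraries 1 to 3 in both groups and do not say what a number stands for. Nothing in the labels says whether the libraries of a group came from separate donors or cultures, so p-values measure only the spread between these libraries, which may be technical.

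The deposited table holds expected counts per gene symbol, which need not be whole, for all 6 libraries. Reads were aligned to the human reference and quantified with RSEM, per the series design text. Bowtie2, FastQC and the build hg38 are named in the submitters' processing notes, and neither their versions nor the gene annotation's release is given in the sources used here. Strand handling is likewise not given, so reads of overlapping genes on opposite strands may not be told apart. RSEM divides a read that matches several genes between them, so the values of genes with near-identical copies, such as FTH1, the AKR1C genes, HBA1 and the tryptase genes TPSAB1 and TPSB2, are uncertain. The library totals were above the read number that the design text names, and no source used here explains the difference.

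The table has 44567 rows, of which 27479 had a total above 0. In 28 rows a spreadsheet had turned the gene name into a date. These rows held between 0.297% and 0.453% of a library's counts and were left out of library sizes and tests. Genes linked to sex were left out of the tests and their scaling for privacy. Counts of table rows, library totals and shares of a library's counts still include them and the date-named rows. HLA genes, immunoglobulin and T cell receptor segments, genes that vary by presence between people, clone-named rows and genes that do not code for protein stayed in the tests and are not named, except for 1 set of clone-named rows that took an unusual share of counts. Symbols were matched to the GENCODE annotation version 29 of GRCh38, the same assembly as hg38, for gene types, positions, GC content and length. Of the list members, 9 were found under an older symbol.

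Library totals ran from 66297030 to 78356591 expected counts. Intervals given for single libraries are exact 95% binomial intervals, and they cover counting error only. Whether libraries of a group were copies of each other was checked with a chi-square comparison of their counts. The statistic per degree of freedom was between 113 and 206 for the 6 pairs within groups, so all libraries were kept as separate samples.

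Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr, which left 17523 genes (13218 protein coding), and libraries were scaled by TMM. RTA-408 was compared with untreated by the robust quasi-likelihood F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Adjusted p-values of genes come from this test unless another is named. Levels are CPM, counts scaled to a common effective library size, given as mean ± SD over 3 libraries, and errors of log2 fold changes are standard errors.

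The design without a pairing term was the main one, since no source states a pairing. Whether the numbers pair the libraries was checked from each library's deviations from its group mean. The correlation across genes was 0.55 for number 1, 0.59 for number 2 and 0.58 for number 3, all above the 0.1 set as the minimum. The numbers were therefore taken to pair the libraries on the evidence of the data alone. A second fit with the number as a replicate block is given beside a result where it changed a call or moved a count by more than 1.5 times.

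A set of 34 gene lists with 715 entries was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. It covered NRF2 targets, T cell programmes, metabolism, stress responses and markers of other blood cells. Adjusted p-values of lists come from camera, with adjustment over the lists, unless another test is named. Beside the number of members past the gene test over all genes stands the number adjusted over the list alone. Named genes were chosen by a rule. It took the 12 largest rises and the 12 largest falls among genes past the threshold, with a mean of at least 1 CPM and the same direction in all 3 number-matched pairs. It added 16 fixed genes of the NRF2 pathway and T cell effector function, and in each list up to 4 measured members of smallest p. Some genes that the rule selects are not reported here. Genes named outside the rule are said to be so. The design, the lists, the rule and the alternatives listed next, but for 2 named there, were fixed before the data were examined.

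The alternatives were other scalings (RLE, library size alone, upper quartile), other low-count filters, DESeq2 1.42.0, limma voom, the replicate block, leaving out each library or each number-matched pair, an inter-gene correlation estimated for each list, and fry. Leaving out mitochondrial and clone-named rows, and removing each library's trend with GC content and length within the replicate block fit, were added after the data had been seen.

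The code was tested on simulated counts for this comparison. Among 17214 genes, the test without the block recovered 1.49% of genes changed by 1.5-fold, 17.9% of those changed by 2-fold and 53.8% of those changed by 4-fold, and 4.55% of its calls were false. With the replicate block, among 17219 genes, these shares were 38.8%, 58.2% and 90.8%, and 9.60% of calls were false. Both lists that were shifted in the simulation were found, and 0 lists without a shifted gene were called. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often the list test calls falsely when the genes of a list are correlated.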

Results

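The data are RNA-seq profiles of human T cells activated for 72 h through CD3 and CD28, the antigen receptor complex and its main costimulatory receptor. Of the 6 libraries, 3 came from cells given 100 pM RTA-408 and 3 from untreated cells. Totals ran from 68890353 to 73488255 expected counts in untreated libraries and from 66297030 to 78356591 in RTA-408 libraries. Mitochondrial genes took 3.17% ± 1.62 of the counts in untreated and 3.43% ± 0.584 in RTA-408 libraries, with the lowest share, 1.33% (exact 95% interval 1.32796 to 1.33334), in untreated replicate 3. A set of 5 clone-named rows, CH507-513H4, took 1.30% of RTA-408 replicate 1 (exact 95% interval 1.29969 to 1.30515) and between 0.0524% and 0.153% of each of the other libraries.

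The comparison asked how an NRF2 activator alters gene expression in activated T cells. RTA-408 raised antioxidant and iron-storage genes controlled by NRF2, among them NQO1 by 6.88-fold, TXNRD1 by 4.89-fold and OSGIN1 by 76.3-fold. It lowered the transcriptional repressor HIC1 by 94.9-fold and the integrin subunit ITGA4 by 4.91-fold. Transcripts of the cytokines TNF and LTA were higher, by 2.59-fold and 2.90-fold. In all, 148 of 17523 genes passed the edgeR threshold, 91 higher and 57 lower with RTA-408. Each of the 148 moved the same way in all 3 number-matched pairs, which selection by this threshold makes likely, so it is no separate support. Of these, 141 code for protein, and 81 rises and 45 falls were at least 2-fold. The replicate block raised the count to 1993 genes, 1045 higher and 948 lower, including 146 of the 148. Leaving out 1 library at a time, in fits without the block, left between 21 genes (without untreated replicate 3) and 84 genes (without RTA-408 replicate 3). With the replicate block, leaving out pair 1, 2 or 3 kept 146, 146 and 147 of the 148 calls.

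Of 34 measured NRF2 targets, 17 rose and 0 fell over all genes tested, and 24 rose when adjusted over the list alone. All 34 had a log2 fold change above 0, with a median of 1.28. NQO1 (ENSG00000181019.12; GRCh38 chromosome 16, 69706996 to 69726951, minus strand), a quinone reductase, went from 18.5 ± 2.08 to 127 ± 9.91 CPM (SD, n = 3; log2 fold change 2.78, SE 0.14, edgeR adjusted p = 0.000949). TXNRD1 (ENSG00000198431.15; chromosome 12, 104215779 to 104350305, plus strand), which encodes thioredoxin reductase, went from 117 ± 5.33 to 571 ± 13.7 CPM (2.29, SE 0.11, edgeR adjusted p = 0.000949). OSGIN1 (ENSG00000140961.12; chromosome 16, 83948282 to 83966332, plus strand) rose from 0.310 ± 0.155 to 23.9 ± 5.87 CPM (6.25, SE 0.42, edgeR adjusted p = 0.00439). SLC7A11 (chromosome 4, 138164097 to 138242349, minus strand), the cystine importer subunit, rose from 1.27 ± 0.426 to 24.8 ± 5.86 CPM (4.28, SE 0.33). GCLC, the catalytic subunit of the first enzyme of glutathione synthesis, rose 2.02-fold and SRXN1 3.84-fold.

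**Figure D1:**
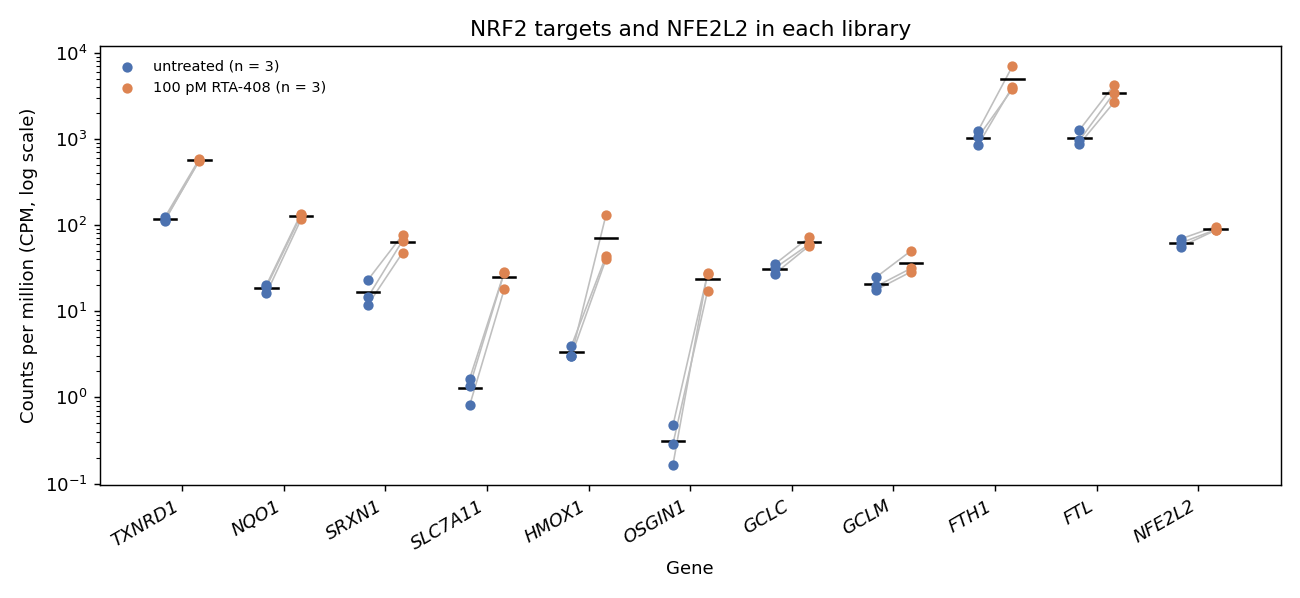
Expression in CPM (log axis) of 10 NRF2 targets and of NFE2L2 in each library, with untreated libraries in blue, RTA-408 libraries in orange (n = 3 each), black bars at group means and grey lines joining libraries of the same number. NQO1 averages 18.5 in untreated and 127 in RTA-408 libraries, and HMOX1 spreads widest among the RTA-408 libraries (71.0 ± 50.9).

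HMOX1, heme oxygenase 1, rose from 3.33 ± 0.527 to 71.0 ± 50.9 CPM (4.41, SE 0.51, edgeR adjusted p = 0.0172), and its adjusted p was 0.0690 with the replicate block, at a log2 fold change of 4.18. The replicate block in DESeq2 kept the call of HMOX1. Without RTA-408 replicate 3 and without the block, the log2 fold change of HMOX1 was 3.64. The ferritin chains FTH1 and FTL, chosen after their values were seen, rose from 1037 ± 193 to 4932 ± 1773 and from 1036 ± 208 to 3431 ± 779 CPM. FTH1 shares reads with near-identical copies, so its level is uncertain. NFE2L2 itself was at 62.7 ± 6.48 and 90.4 ± 4.73 CPM (0.53, edgeR adjusted p = 0.118, or 0.0043 with the replicate block). KEAP1, its repressor, had a log2 fold change of 0.35 (edgeR adjusted p = 0.447, or 0.0409 with the replicate block), and GCLM one of 0.83 (0.235, or 0.000794 with the replicate block). The list ranked above other genes (camera adjusted p = 4.21e-31; adjusted p = 0.495 with an estimated correlation). Without single libraries, NQO1, TXNRD1, OSGIN1 and SLC7A11 kept their calls throughout, HMOX1 reached an adjusted p of 0.123 without untreated replicate 3, SRXN1 0.148 without untreated replicate 2, and GCLC lost its call in all 6 fits (up to 0.119 without untreated replicate 2). Those fits had no block, and with the replicate block on all libraries GCLC passed (edgeR adjusted p = 5.75e-05).

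Of the other large rises, PIR is also a member of the NRF2 list. FUT7, the fucosyltransferase that builds selectin ligands on leukocytes, rose from 2.19 ± 0.534 to 55.2 ± 21.8 CPM (4.66, SE 0.34, edgeR adjusted p = 0.00439). The membrane enzyme carboxypeptidase M, whose gene symbol is also CPM, rose 18.2-fold, the pannexin PANX2 14.2-fold, the iron-binding nuclear protein PIR 13.5-fold and the co-receptor RGMB 15.2-fold. SLC12A8, CUEDC1 and VWF rose 27.6-fold, 23.7-fold and 22.9-fold from levels under 1 CPM, and without RTA-408 replicate 3 the log2 fold change of SLC12A8 went from 4.79 to 3.97. HPD, an enzyme of tyrosine breakdown, went from 0.0458 ± 0.0679 to 2.82 ± 0.818 CPM, so its fold rests on few reads (log2 fold change 5.87, or 8.31 without untreated replicate 1). FUT7, CUEDC1 and VWF kept their calls in all leave-one-out fits. The highest adjusted p of the others was 0.173 for HPD and 0.156 for PIR (both without untreated replicate 2), and without untreated replicate 3 it was 0.146 for SLC12A8, 0.109 for RGMB, 0.0911 for PANX2 and 0.0624 for the carboxypeptidase gene.

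Among the 12 largest falls, HIC1 (ENSG00000177374.12; chromosome 17, 2054154 to 2063241, plus strand) went from 103 ± 33.4 to 1.09 ± 0.356 CPM (SD, n = 3; -6.57, SE 0.37, edgeR adjusted p = 0.0017). CD38 (ENSG00000004468.12; chromosome 4, 15778275 to 15853230, plus strand), an NAD-degrading ectoenzyme of activated lymphocytes, went from 103 ± 12.7 to 5.65 ± 4.95 CPM (-4.18, SE 0.62, edgeR adjusted p = 0.0363, or -4.49 and 0.0738 with the replicate block), and its log2 fold change was -5.18 without RTA-408 replicate 2. The replicate block in DESeq2 kept the call of CD38. The transcriptional repressor GFI1 fell from 95.3 ± 2.35 to 10.01 ± 3.99 CPM, DDIT4, an inhibitor of mTORC1, from 233 ± 63.5 to 28.7 ± 4.29, and ASB2, a ubiquitin ligase subunit, from 317 ± 21.4 to 40.7 ± 18.8. The ATP-gated channel P2RX5 fell 9.65-fold, the integrin subunit ITGAX 7.36-fold (log2 fold change -2.88, or -2.27 without untreated replicate 2) and the adhesion molecule CEACAM1 6.84-fold. SIAH3, NAPSA, DENND6B and RNF207 fell 13.6-fold, 7.73-fold, 7.36-fold and 6.95-fold. HIC1, DDIT4 and DENND6B kept their calls in all leave-one-out fits, and ITGAX and RNF207 lost theirs in all 6 (up to 0.166 and 0.134 without RTA-408 replicate 2). CD38, ASB2, GFI1 and P2RX5 reached an adjusted p of 0.134, 0.0911, 0.0513 and 0.0528 without untreated replicate 3, NAPSA 0.178 without RTA-408 replicate 2, and SIAH3 and CEACAM1 0.0535 and 0.0730 without untreated replicate 2.

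Of the effector cytokines, TNF and LTA rose. TNF went from 8.85 ± 1.44 to 22.96 ± 3.50 CPM (1.37, SE 0.19, edgeR adjusted p = 0.0278) and LTA, lymphotoxin alpha, from 21.0 ± 6.79 to 60.9 ± 2.52 (1.54, SE 0.23, edgeR adjusted p = 0.0358). They were the 2 of 19 measured effector cytokines and chemokines past the threshold, and 5 rose and 3 fell when adjusted over the list alone. The fit with the replicate block gave 9 rises and 2 falls. IFNG was at 5.24 ± 4.38 and 16.7 ± 15.1 CPM (1.67, edgeR adjusted p = 0.479). It was higher in 3 of 3 pairs (2.49 to 8.13, 2.94 to 7.77 and 10.3 to 34.1 CPM) and past the threshold with the replicate block (edgeR adjusted p = 2.99e-05). Its log2 fold change was 0.60 without RTA-408 replicate 3 and 2.63 without untreated replicate 3. Those fits had no block and split pair 3, so the higher level of that pair enters the fold change. IL5 had a log2 fold change of -2.85 from 0.283 ± 0.114 CPM (edgeR adjusted p = 0.0832, or 0.0151 with the replicate block). IL2 and IL17A, with 17 and 12 expected counts in all 6 libraries together, were not tested. The list ranked above other genes (camera adjusted p = 0.0162; adjusted p = 0.631 with an estimated correlation), and its adjusted p was 0.0659 without untreated replicate 1 and 0.0542 without RTA-408 replicate 1. TNF lost its call in all 6 leave-one-out fits without the block and LTA in 5 (up to 0.129 and 0.170 without untreated replicate 3). With the replicate block on all libraries both passed (edgeR adjusted p = 9.15e-05 and 0.000163).

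Of 18 cytotoxic effector genes, 0 passed over all genes or over the list alone, while with the replicate block 2 rose and 7 fell. Granzyme B (GZMB) was at 129 ± 105 CPM in untreated and 31.1 ± 37.1 in RTA-408 libraries (SD, n = 3; -2.05, edgeR adjusted p = 0.499, or 0.0869 with the replicate block), lower in 3 of 3 pairs, with a log2 fold change of -3.72 without RTA-408 replicate 3 and of -1.13 without untreated replicate 3. Granzyme A (GZMA) was at 43.1 ± 30.9 and 13.3 ± 10.05 CPM (-1.70, edgeR adjusted p = 0.47, or 0.000694 with the replicate block), with -2.38 and -0.97 without the same libraries. Those fits had no block and split pair 3, whose libraries had the highest level of both genes in their groups. In pairs 1 to 3 GZMB went from 75.2 to 14.2, 61.8 to 5.45 and 250 to 73.6 CPM. GZMA went from 36.2 to 13.6, 16.4 to 3.06 and 76.9 to 23.2 CPM. GZMB did pass with the replicate block in DESeq2 (DESeq2 adjusted p = 1.94e-06). In edgeR with the block, it passed without pair 2 or pair 3 (edgeR adjusted p = 0.000199 and 0.00326) but not without pair 1. GZMM had a log2 fold change of -0.47 and CRTAM of 0.62, both past the threshold with the replicate block (0.0247 and 0.00281). The list missed the threshold (camera adjusted p = 0.316) and passed it, ranking lower, without RTA-408 replicate 3 (0.0289) or untreated replicate 2 (0.0349). The list of NK cell markers also ranked lower without those same libraries (0.0337 and 0.0189) and with the replicate block (camera adjusted p = 0.0205, and 0.660 with an estimated correlation). Its summed CPM was nonetheless higher with RTA-408 in each pair (111 and 120, 80.0 and 115, 264 and 349 in untreated and RTA-408). The member FGFBP2 alone went from 45.2 to 75.5, 39.4 to 93.2 and 92.1 to 201 CPM in pairs 1 to 3. It rose by more than the sum did in each pair, so the sum of the other members was lower with RTA-408. Of the 14 members, 4 had a log2 fold change above 0 without the block, and the median was -0.47.

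**Figure D2:**
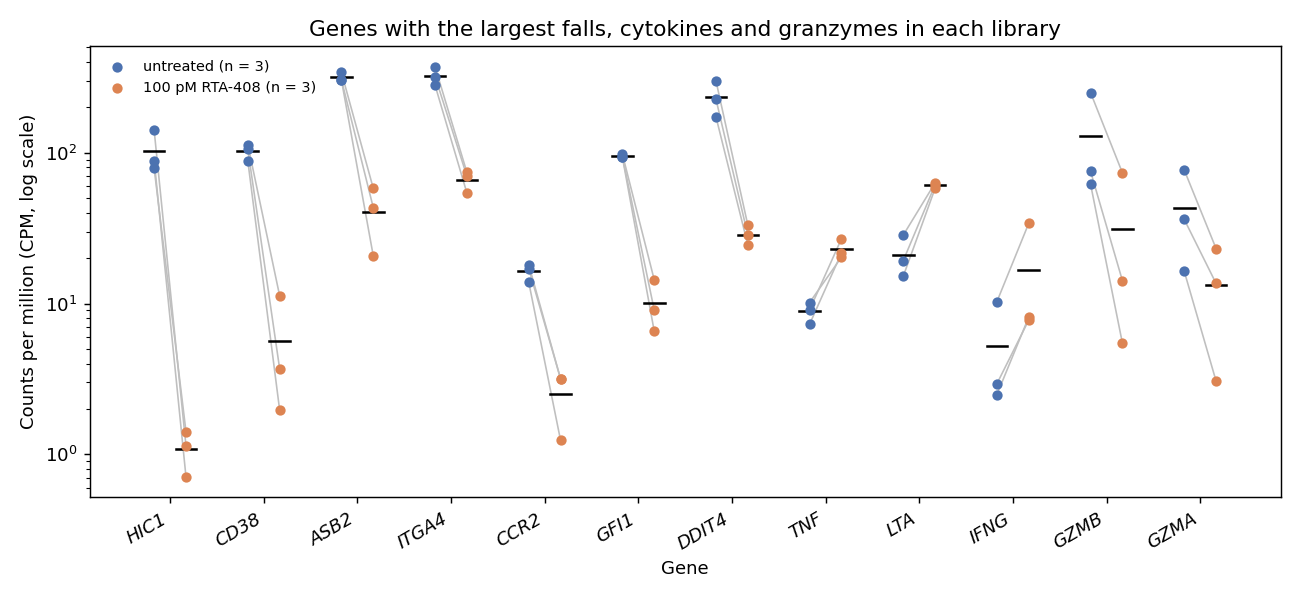
Expression in CPM (log axis) in each library of genes with large falls and of cytokine and granzyme genes, with untreated libraries in blue, RTA-408 libraries in orange (n = 3 each), black bars at group means and grey lines joining libraries of the same number. HIC1 averages 103 in untreated and 1.09 in RTA-408 libraries, and the GZMB libraries spread widely within each group (129 ± 105 and 31.1 ± 37.1).

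Among 18 genes of T cell trafficking and gut homing, 0 rose and 2 fell, and 1 rose and 4 fell when adjusted over the list alone. Under the replicate block 2 rose and 9 fell. ITGA4 (ENSG00000115232.13; chromosome 2, 181457202 to 181536187, plus strand), the alpha 4 chain of the gut-homing integrin, fell from 324 ± 45.8 to 66.03 ± 10.6 CPM (SD, n = 3; SE of the log2 fold change 0.17, edgeR adjusted p = 0.00439). The chemokine receptor CCR2 fell from 16.3 ± 2.21 to 2.53 ± 1.12 CPM (-2.69, SE 0.37, edgeR adjusted p = 0.0317). ICAM1 had a log2 fold change of -0.92 (edgeR adjusted p = 0.0899, or 0.000945 with the replicate block). The list ranked below other genes (camera adjusted p = 0.00535; adjusted p = 0.794 with an estimated correlation). Its adjusted p was 0.0687 without untreated replicate 1 and 0.0644 without RTA-408 replicate 3, and CCR2 reached 0.132 without untreated replicate 3.

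All 22 measured hypoxia and HIF target genes had a log2 fold change below 0, with a median of -1.06. Over all genes tested 0 passed, 8 fell when adjusted over the list alone, and 13 fell with the replicate block. EGLN1, an oxygen-sensing prolyl hydroxylase, was at 48.9 ± 9.69 and 19.9 ± 5.06 CPM (-1.30, SE 0.23, edgeR adjusted p = 0.062, or 1.29e-05 with the replicate block), and the mitophagy receptor BNIP3 at 57.3 ± 14.4 and 26.6 ± 13.1 (-1.11, SE 0.34, edgeR adjusted p = 0.264, or 0.000164 with the replicate block). Of 22 glycolysis genes 0 rose and 1 fell, 0 rose and 2 fell when adjusted over the list alone, and 10 fell with the replicate block. The lactate exporter SLC16A3 fell from 75.1 ± 6.64 to 20.6 ± 8.13 CPM (-1.87, SE 0.27, edgeR adjusted p = 0.0348). Hexokinase 2, HK2, had a log2 fold change of -1.56 (edgeR adjusted p = 0.0731, 0.0318 with the replicate block, and 0.0124 without RTA-408 replicate 3). Both lists ranked below other genes (camera adjusted p = 1.08e-10 for hypoxia and 1.04e-05 for glycolysis; adjusted p = 0.631 and 0.794 with an estimated correlation). Without untreated replicate 3, the library of lowest mitochondrial share, they had adjusted p-values of 6.89e-07 and 0.00915, and SLC16A3 had one of 0.144.

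Neither oxidative phosphorylation (37 measured) nor cholesterol biosynthesis (23) had a member past the threshold over all genes or over the list alone, and the camera adjusted p was 0.219 and 0.908. Their median log2 fold changes were -0.09 and -0.08. STARD4, a cholesterol carrier of the second list, passed with the replicate block (-0.52, edgeR adjusted p = 0.0215). The 13 mitochondrially encoded genes had 0 members past any of these thresholds, and the camera adjusted p was 0.219. Without untreated replicate 1 the first 2 lists passed (7.18e-05 and 0.0325), and without untreated replicate 2 the mitochondrial list did (0.00297).

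Log2 fold changes had a median of 0.51 among T cell activation genes, 0.26 among NF-kB targets and 0.49 among genes of the immediate early and handling stress list, which also respond to the handling of cells. Of 22 activation genes, 0 rose and 1 fell, which was CD38, while 4 rose and 1 fell when adjusted over the list alone, and 10 rose and 1 fell with the replicate block. That fall was not CD38 (edgeR adjusted p = 0.0738 with the replicate block) but the transcription factor NFATC1, named after its values were seen (-0.47, edgeR adjusted p = 0.0195 with the replicate block and 0.701 without it). EGR2, a transcription factor induced by the T cell receptor, was at 20.1 ± 8.58 and 74.2 ± 19.97 CPM (1.88, SE 0.35, edgeR adjusted p = 0.0681, or 1.52e-06 with the replicate block). Of 23 NF-kB targets 2 rose, TNF and LTA, and 0 fell; 6 rose and 1 fell when adjusted over the list alone, and 7 rose and 1 fell with the replicate block. NFKBIA, the inhibitor of NF-kB, had a log2 fold change of 0.99 (edgeR adjusted p = 0.15, or 0.00337 with the replicate block). Of 15 immediate early and handling stress genes 0 passed, 2 rose when adjusted over the list alone, and 8 rose and 1 fell with the replicate block. The phosphatase DUSP2 was at 24.7 ± 7.92 and 55.9 ± 6.81 CPM (edgeR adjusted p = 0.0866, or 6.7e-05 with the replicate block). The activation, NF-kB and immediate early and handling stress lists ranked above other genes (camera adjusted p = 0.00535, 0.00245 and 0.000559; adjusted p = 0.794, 0.794 and 0.631 with an estimated correlation), and the first had an adjusted p of 0.156 without untreated replicate 1.

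T cell receptor signalling (21 measured) and the IL-2 and STAT5 response (18) had 0 members past the threshold over all genes. Over the list alone 1 rose and 2 fell in the first and 0 rose and 4 fell in the second, and with the replicate block 2 rose and 3 fell and 2 rose and 4 fell. CD4 had a log2 fold change of -0.56 (edgeR adjusted p = 0.114, or 0.00852 with the replicate block), and SOCS3, a feedback inhibitor of cytokine signalling, one of -1.54 (0.0791, or 0.00224 with the replicate block). The camera adjusted p was 0.301 and 0.138, and that of the second was 0.0325 without untreated replicate 1.

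Log2 fold changes had a median of 0.48 among p53 targets and of -0.17 among cell cycle genes. Of 21 p53 targets and apoptosis genes 0 passed, 5 rose when adjusted over the list alone, and 11 rose with the replicate block. The apoptosis inducer BBC3 was at 10.3 ± 2.34 and 21.4 ± 4.31 CPM (1.05, edgeR adjusted p = 0.106, or 0.000163 with the replicate block). CDKN1A, the cell cycle inhibitor p21, had a log2 fold change of 1.04 (0.245, or 0.000757 with the replicate block). The list ranked above other genes (camera adjusted p = 8.19e-06; adjusted p = 0.631 with an estimated correlation). Of 35 cell cycle genes 0 passed over all genes or over the list alone and 2 fell with the replicate block, the replication factors MCM2 (-0.49, edgeR adjusted p = 0.0409) and GINS2 (-0.52, 0.0123). That list ranked below other genes (camera adjusted p = 0.00535; adjusted p = 0.798 with an estimated correlation). Its adjusted p was 0.365 without untreated replicate 3 and 0.126 without RTA-408 replicate 1 or RTA-408 replicate 2.

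Ribosomal protein genes took 9.06% ± 0.820 of counts in untreated and 10.5% ± 0.979 in RTA-408 libraries (SD, n = 3). Of 37 measured 0 passed over all genes, over the list alone or with the replicate block, and the list ranked above other genes with a median of 0.24 (camera adjusted p = 6.92e-07; adjusted p = 0.794 with an estimated correlation). The 12 replication-dependent histones likewise had 0 members past any of these thresholds, and the list ranked higher (camera adjusted p = 0.0335; adjusted p = 0.794 with an estimated correlation). HIST1H4C was at 0.209 ± 0.0637 and 0.889 ± 0.928 CPM (2.07, or 0.77 without RTA-408 replicate 1). The histone list had an adjusted p of 0.481 without RTA-408 replicate 1, the library rich in clone-named rows, of 0.0510 without untreated replicate 1 and of 0.0597 without untreated replicate 2.

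The ATF4 and integrated stress response list (25 measured) had 1 rise, SLC7A11, and 1 fall, DDIT4, and over the list alone 2 rises and 1 fall. The replicate block gave 3 rises and 3 falls. The ER stress (20), heat shock (18) and interferon (35) lists had 0 members past the threshold over all genes. Over the list alone 1 rose in each of the first 2 and 1 fell in the third, and with the replicate block 2 rose, 4 rose and 1 fell, and 6 rose and 3 fell. GBP4, an interferon-induced GTPase, was at 181 ± 12.6 and 88.7 ± 18.7 CPM (edgeR adjusted p = 0.0516, or 0.000765 with the replicate block). The camera adjusted p of the 4 lists was 0.908, 0.908, 0.16 and 0.607, and that of the heat shock list was 0.0474 without RTA-408 replicate 1. The medians of the ATF4 and ER stress lists, -0.10 and -0.12, lay below 0 while camera placed both above other genes.

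**Figure D3:**
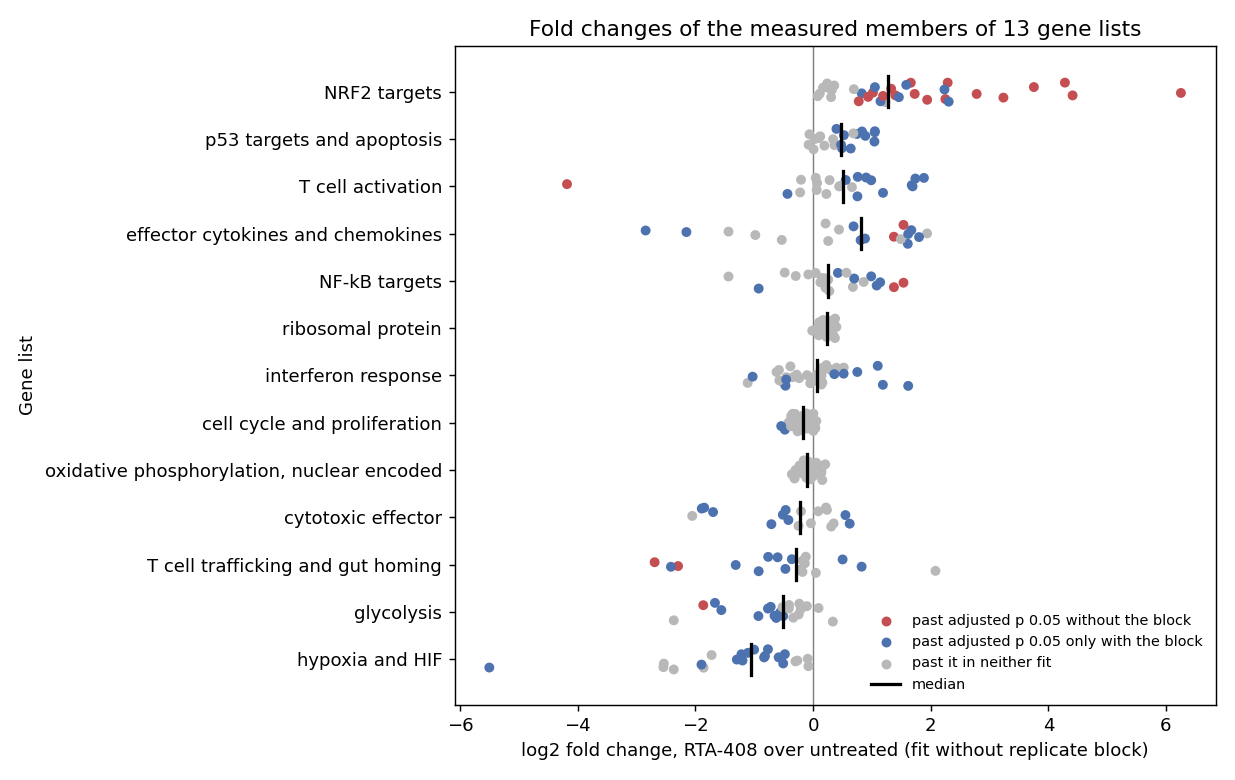
Log2 fold changes, RTA-408 over untreated, of the measured members of 13 gene lists, 1 point per gene and a black line at the median. Points are red past the edgeR threshold, blue past it only with the replicate block and grey otherwise, and the medians run from 1.28 for NRF2 targets to -1.06 for hypoxia genes.

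Lists of T cell subsets and states had few members past the threshold. Of the Th1 (12 measured), Th2 (11), Th17 (12), regulatory (13), inhibitory receptor (15) and naive and memory (15) lists, 1 member passed over all genes. It was AHR in the Th17 list, the aryl hydrocarbon receptor, which rose from 32.3 ± 0.772 to 83.0 ± 12.6 CPM (SD, n = 3; 1.36, SE 0.14, edgeR adjusted p = 0.0111) and reached 0.0603 without untreated replicate 2. Adjusted over the list alone, 2 Th1 genes, 1 Th2, 1 Th17, 1 regulatory and 1 inhibitory receptor gene fell, and 2 Th17 genes and 1 naive or memory gene rose. With the replicate block 3 Th1 genes rose and 5 fell, 1 Th2 gene rose and 2 fell, 2 Th17 genes rose and 4 fell, 2 regulatory genes rose and 2 fell, 2 inhibitory receptor genes rose and 3 fell, and 1 naive or memory gene rose. HAVCR2, the inhibitory receptor TIM-3, was at 27.5 ± 5.85 and 15.4 ± 4.38 CPM (edgeR adjusted p = 0.221, or 0.000619 with the replicate block). The camera adjusted p of the 6 lists lay between 0.139 and 0.908, and that of the naive and memory list was 0.00604 without RTA-408 replicate 3. In the Th2 list the median was 0.26 and the mean -0.03, and in the Th17 list both lay below 0 while camera placed it above other genes.

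Markers of other blood cells had 0 members past the threshold over all genes. Their lists were B cell (13 measured), monocyte and macrophage (7), dendritic cell (7), NK cell (14), platelet and erythroid (7) and granulocyte and mast cell (10). Adjusted over the list alone 1 B cell gene rose and 1 fell, 1 dendritic cell gene rose, and 0 moved in the other lists. With the replicate block the NK list ranked lower (camera adjusted p = 0.165 without the block and 0.0205 with it), and the platelet and erythroid list (0.095 and 0.00137) and the granulocyte and mast cell list (0.063 and 0.00409) ranked higher. With an estimated correlation in the replicate block fit their adjusted p = 0.660, 0.435 and 0.435. Without the block the 3 lists also passed without RTA-408 replicate 3 (0.0337, 9.16e-05 and 0.00348), the first 2 without untreated replicate 2 (0.0189 and 0.0262), and the last 2 without untreated replicate 1 (0.0349 and 0.0175). In those lists 2 genes rose and 4 fell, 4 rose, and 2 rose with the replicate block. In the NK list NCR3 was at 18.2 ± 1.85 and 9.14 ± 3.88 CPM (edgeR adjusted p = 0.238, or 0.0445 with the replicate block). FGFBP2 in the same list went the other way, at 58.9 ± 28.9 and 123 ± 67.8 CPM (0.433, or 0.000145). The hemoglobin chain HBD was at 0.902 ± 0.567 and 3.62 ± 2.87 (0.428, or 0.00133), and the tryptase TPSB2 at 0.370 ± 0.288 and 1.43 ± 1.37 (0.555, or 0.00814). The log2 fold change of HBD was 2.00, or 1.31 without RTA-408 replicate 1, and that of TPSB2 was 1.93, or 0.86 without RTA-408 replicate 2 and 2.62 without untreated replicate 2. CD79A in the B cell list was at 39.7 ± 2.76 and 15.3 ± 5.60 (edgeR adjusted p = 0.0703, 0.000665 with the replicate block and 0.0362 without RTA-408 replicate 1). MS4A1 in the same list was at 10.8 ± 12.8 and 21.6 ± 25.5 (edgeR adjusted p = 0.866, or 0.0314 with the replicate block). Its log2 fold change was above 0, and was -0.55 without RTA-408 replicate 1 and 2.63 without untreated replicate 1. Like those of HBD and TPSB2, these fits had no block and split a pair. Within pairs 1 to 3 MS4A1 went from 25.4 to 50.5, 5.35 to 12.7 and 1.63 to 1.75 CPM. In the replicate block fit 2 B cell genes rose and 1 fell, 1 monocyte gene fell and 1 dendritic cell gene rose, and the camera adjusted p of these lists was 0.929, 0.327 and 0.177 without the block. That of the dendritic cell list was 0.0406 without RTA-408 replicate 3 and 0.0320 without untreated replicate 2.

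In total 12 of 34 lists passed with the preset correlation and 15 with the replicate block. With an estimated correlation 0 passed in either fit. By fry, which tests each list on its own, the NRF2 list alone passed without the block (fry adjusted p = 0.0147). With the replicate block fry also passed the hypoxia, p53, trafficking, dendritic cell and platelet and erythroid lists (fry adjusted p = 0.0424 each). Of the 10 splits of the 6 libraries into 3 and 3, 7 gave at least 12 lists, the real one included.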

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

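Of the alternatives in this section, leaving out mitochondrial and clone-named rows and the GC and length correction with the replicate block were chosen after the results had been seen. After that correction lists were tested and single genes were not. Of the 148 genes called, 0 changed sign under the other scalings, filters and tools, with the replicate block, without single libraries or pairs, or without those rows, and 129 or more stayed called under RLE (146), library size alone (136), upper quartile (135), no low-count filter (141), at least 1 CPM in 3 libraries (138), DESeq2 (147), limma voom (129), the replicate block (146) and the fit without mitochondrial and clone-named rows (147). Counts of calls lay between 141 and 177 under these scalings, under limma voom, under the stricter filter and without mitochondrial and clone-named rows. They moved further under no low-count filter (228 genes, 144 higher), DESeq2 (738 genes, 413 higher and 325 lower), the replicate block (1993, 1045 and 948) and the replicate block in DESeq2 (2160, 1160 and 1000). With the replicate block and without pair 1, 2 or 3 in turn, 1017 (513 higher, 504 lower), 834 (470 and 364) and 1369 (758 and 611) genes were called. These fits kept 146, 146 and 147 of the 148 calls. Removing a shared deviation of number-matched libraries is what the block does by construction; for the other alternatives the cause was not tested. Leaving out each library in turn, with fewer samples and without the block, left 21 to 84 genes, 14 to 52 higher and 7 to 34 lower. The paired fit ended the call of 2 of the 35 genes past the threshold that the naming rule selects, HMOX1 and CD38, and of 0 of the 12 lists, and it ended no other call among these genes and lists. The log2 fold changes of these 2 genes stayed large there, at 4.18 and -4.49. The replicate block in DESeq2 kept all 148 calls. Testing with no low-count filter ended the calls of HMOX1 (edgeR adjusted p = 0.0526), PIR (0.132) and CD38 (0.176) and of the effector cytokine list (camera adjusted p = 0.0567), and it added the platelet and erythroid list (0.0149) and the granulocyte and mast cell list (0.0442). Library size alone added the last of these (0.0442). HPD lost its call under library size alone and upper quartile (edgeR adjusted p = 0.0575 and 0.0579), and limma voom ended those of SLC12A8 and ITGAX (limma adjusted p = 0.0611 and 0.0853). The ribosomal and histone lists, fitted with the replicate block, lost their calls without pair 1 (camera adjusted p = 0.136 and 0.285) and the cell cycle list without pair 2 (0.0727). Of the 35, 11 kept their call in all 6 leave-one-out fits and 6 in 0 of them. The 12 list calls became 0 with an estimated correlation, with and without the replicate block, and 1 by fry, and ranged from 10 to 17 without single libraries; 0 of the 12 changed direction. The real grouping gave 148 genes, and the highest of the other 9 splits of the 6 libraries gave 0; 1 split of 10 reached 148. With the replicate block it gave 1993 genes against 0, 1 of 4 splits that part all pairs. These splits are too few for a share under 0.05. For lists, 7 of 10 splits reached 12 and the highest other gave 17, and with the replicate block the real grouping and the highest of the other splits that part all pairs gave 15 each, so the number of lists does not set the real grouping apart. Whether a preset correlation that is too low or a structure of the samples lies behind this was not tested. What depth limits was not tested either. At 66297030 counts or more per library, the simulated test found 17.9% of 2-fold changes without the block and 58.2% with it.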

Other observations

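The genes named here outside the rule, the retinoic acid and aryl hydrocarbon receptor lists, the GC and length correction, the scaling without the 20 most abundant genes, the test of HIF1A, the median of hypoxia genes outside glycolysis and the ratio of CD8A to CD4 were chosen after the results had been seen. Several genes outside the fixed lists also passed the threshold. Transcripts of the costimulatory ligands TNFSF4 (OX40 ligand) and TNFSF14 (LIGHT) rose from 4.09 ± 0.948 to 15.0 ± 3.65 and from 22.9 ± 1.002 to 43.9 ± 3.78 CPM (SD, n = 3; edgeR adjusted p = 0.0322 and 0.0212). LMNA, which encodes lamins A and C, rose from 59.9 ± 24.0 to 475 ± 194 CPM (2.99, SE 0.43, edgeR adjusted p = 0.0348). The prostaglandin E2 receptor PTGER4 and the phosphatase DUSP4 had log2 fold changes of 1.14 and 1.36 (edgeR adjusted p = 0.0363 and 0.0198). Each of these genes moved the same way in 3 of 3 pairs, as did all 148 genes past the threshold.

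All 22 hypoxia genes and most glycolysis genes had log2 fold changes below 0. A trend with GC content or gene length did not account for the hypoxia values, whose median was -1.16 in the replicate block fit after that trend was removed. Nor did reads taken up by a few abundant genes, since the median was -1.10 when library size left out the 20 most abundant genes; the glycolysis list was not tested with that scaling. Outside the 3 glycolysis genes that the hypoxia list holds, the other 19 members had a median of -1.11, which is no separate test because all members were already seen to lie below 0. Lower activity of HIF, the oxygen-responsive factor, may lie behind these values. The HIF1A transcript had a log2 fold change of -0.23 (SE 0.10, edgeR adjusted p = 0.176 with the replicate block), which leaves a change in the transcript open. A transcript level does not measure the activity of the protein, and oxygen and cell density of the cultures were not analysed here.

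HIC1, CD38, ASB2, ITGA4 and RARRES3, all among the genes that fell, are known to be induced by retinoic acid, and a candidate explanation is weaker retinoic acid receptor signalling. Of the members of a retinoic acid list whose values had not been seen, 6 were measured and 3 were below 0, with a median of -0.39 in the replicate block fit, which does not decide it. CCR9 (-2.11) and DHRS3 (-0.84) fell in that fit (edgeR adjusted p = 0.00875 and 0.00543, against 0.428 and 0.208 without the block) while RARG rose (0.78, edgeR adjusted p = 0.000393, against 0.105). After a trend with GC content and length was removed, the medians were -3.09 over the 5 genes chosen because they fell, the highest of which was at -1.59, -0.36 over the 6 others and -1.59 over the whole measured list. That trend therefore did not account for the fall of the 5. The receptor gene RARA rose from 40.8 ± 3.84 to 90.5 ± 8.22 CPM (SD, n = 3).

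CYP1B1, a target of the aryl hydrocarbon receptor, rose from 22.9 ± 10.7 to 164 ± 26.0 CPM (SD, n = 3; 2.84, edgeR adjusted p = 0.0198), and the receptor gene AHR rose as well. Higher activity of this receptor is a candidate explanation. The 5 measured targets whose values had not been seen were all above 0 in the replicate block fit with a median of 0.99, and CYP1A1 (1.52), TIPARP (0.99) and AHRR (0.79) passed the threshold there (edgeR adjusted p = 0.000396, 0.000261 and 0.00284, against 0.0619, 0.0548 and 0.213 without the block). Technical explanations for this pattern were not tested, and the NRF2 target NQO1 belongs to both target lists, so the pathways are not separated by it.

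The log2 ratio of CD8A to CD4 was higher with RTA-408 by 0.39 on average over the 3 number-matched pairs (SD 0.24; 0.14, 0.61 and 0.44 in pairs 1 to 3).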
